A study of Homo sapiens with 6 samples.

How the data were processed

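Gene expression was measured by RNA-seq in CD8+ T cells sorted from human tonsils. The 6 libraries come from 3 sorted populations of the same 2 donors, with 2 libraries per population. The populations were CXCR5+CD45RA−CD8+ cells, CXCR5−CD45RA−CD8+ cells and CD45RA+CD8+ cells. Per the labels' protocols, total RNA was extracted with Trizol and a column kit for very small samples, amplified with the SMARTer Universal Low Input kit and made into stranded TruSeq Total RNA libraries that were sequenced as paired ends on a HiSeq instrument.

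The authors deposited 1 table of variance-stabilised log2 values for 23368 gene symbols, with 1 column per library. Trimmomatic, TopHat, HTSeq and DESeq are named, with the genome build hg19, per the submitters' processing notes. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and of an antisense partner cannot be separated. Values of near-identical genes, such as the replication-dependent histones, the guanylate-binding proteins, CCL3, CCL4 and XCL1, are uncertain because reads may be split between copies. No annotation of the hg19 build was used here, and genes are given by the symbols of the deposited table without coordinates. A table of gene names matched 19656 of the symbols.

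The variance-stabilising transformation gives a gene without reads the same lowest value in every library, 3.11 on the log2 scale. Inverting the transformation and dividing by the value of 1 read in each library gave whole read counts for 100% of the values, within a tolerance of 0.001 of a read. The recovered totals ranged from 3596048 to 24224776 reads, a ratio of 6.74 between the deepest and the shallowest library. Recovered reads were used to give the depth, the RPM of a gene (its reads scaled to the library total, averaged over the 2 libraries of a population) and an alternative test. The transformation shrinks differences of genes with few reads, so differences of the variance-stabilised values, given in log2 units, understate the fold change of such genes.

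Each comparison was fitted with limma 3.58.1 (R 4.3.3) on the deposited values as they stand, with all 6 libraries in 1 fit and the population means as the only terms. Genes were tested if their mean lay at least 1 log2 unit above the lowest value, which left 16266 genes. The fit had 3 residual and 4.55 prior degrees of freedom. Calls were made two-sided at a Benjamini-Hochberg adjusted p under 0.05. All p-values rest on the spread between 2 donors per population. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and plots.

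The main tests, the gene lists, the rule for the genes named and 14 alternatives were fixed before the data were examined. There were 23 lists, of which 21 had at least 3 tested members. They covered T cell programmes, metabolism, cell cycle, histones and interferon response, and markers of B, plasma, CD4 and regulatory T, NK, innate-like T, myeloid, and epithelial and stromal cells. Erythrocyte and platelet markers had 2 tested members and mitochondrially encoded transcripts had 0, so neither list was tested. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 21 lists of a comparison. Each was also tested with the correlation estimated from the data and with fry, which asks whether the genes of a list move, on balance, 1 way. With an estimated correlation 0 lists passed in each of the 3 comparisons. The estimate lay above the preset for most lists. It was 0.942 for interferon response, 0.343 for inhibitory receptors, 0.327 for activation and 0.315 for histone genes. For such lists the preset can give p-values that are far too small.

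The rule for named genes takes CXCR5, CD8A, CD8B and PTPRC, then in each direction the 12 genes with the largest difference among those past the threshold and of the same sign in both donors, and then up to 6 members of each list past its threshold and up to 2 of each other list. Where fewer than 12 genes passed in a direction, the places were filled by the smallest unadjusted p, and those genes are said not to pass. The text names a part of the genes the rule gave, and that part was picked after their values were seen. Y-linked genes, transcripts of X inactivation, HLA and KIR genes, GSTM1, GSTT1 and receptor gene segments, 147 symbols in all, were never named. Results that need some further genes are not reported here, and the tests of B cells and of the shallow library in the closing part were run on the genes left after that. Unnamed loci, open reading frames, antisense genes and similar symbols were left out of the 12 largest.

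Those 14 were the donor as a block, no filter, a stricter filter of 2 units, an intensity trend, robust variance estimates, quantile normalisation, median centring, a fit of the compared libraries alone, and leaving out each of the 6 libraries in turn. The lists were also run with the other set tests named above. Leaving out a library assumes that the lone remaining library of its population varies like the other groups. These fits had no donor term. Without a library of a compared population the donors are uneven, so a difference between donors can move the result. In a comparison that does not use that population, the result is the same fit as the compared libraries alone and is no separate check. Limma-voom on the recovered reads, scaled by the recovered size factors, scaled by total reads, or with the donor block, was added after seeing the data.

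The labels give the same donor for libraries that share a replicate number, so the numbers pair the samples. Deviations from the population means correlated across genes between libraries of the same donor, with r = 0.169 between CXCR5+ and CXCR5− cells, r = 0.092 between CXCR5+ and CD45RA+ cells and r = 0.475 between CXCR5− and CD45RA+ cells. Genes are not independent replicates in these values. Replicates were also checked for being 1 library deposited again. Their reads differed beyond sampling noise, with a chi-square per degree of freedom of 24.5, 29.3 and 12.4 in CXCR5+, CXCR5− and CD45RA+ cells.

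The fit was tested on simulated data drawn from the means and depths of these libraries. Changes were planted only in genes above a floor of mean reads, so the shares do not cover genes with few reads. Genes with few reads drew their spread from genes with more reads, and no donor effect was simulated. For CXCR5+ against CXCR5− cells it recovered 9.09% of 66 genes changed by 1 log2 unit, 71.6% of 67 changed by 2 and 89.6% of 67 changed by 3. There 16496 genes were tested. For CXCR5+ against CD45RA+ cells it recovered 3.03%, 67.2% and 86.6% among 16447 genes. For CXCR5− against CD45RA+ cells it recovered 7.58%, 65.7% and 91.0% among 16477 genes. The unchanged genes called numbered 2, 9 and 6 in that order of comparisons. The libraries were amplified without molecular identifiers, so intervals and floors of read counts cover counting error only.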

Results

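The transcriptomes of 3 CD8+ T cell populations sorted from human tonsils were compared. CXCR5 is the chemokine receptor that guides lymphocytes into B cell follicles, and CD45RA is an isoform of the phosphatase CD45 that naive T cells carry and most memory cells lose. The sorts gave CXCR5+CD45RA−CD8+ cells, CXCR5−CD45RA−CD8+ cells and CD45RA+CD8+ cells, called CXCR5+, CXCR5− and CD45RA+ cells here, each from the same 2 donors. The recovered depths of replicates 1 and 2 were 17491284 and 7771847 reads for CXCR5+ cells, 5714877 and 24224776 for CXCR5− cells, and 7769092 and 3596048 for CD45RA+ cells. The first principal component of the tested genes held 52.5% of the variance. It placed the CD45RA+ libraries at 59.7 and 44.7 and the 4 other libraries between -38.0 and -7.74. The second component held 18.3% and set the donors apart. For CXCR5+, CXCR5− and CD45RA+ cells it lay at 16.0, 24.7 and 22.2 in replicate 1. In replicate 2 it lay at -4.87, -25.8 and -32.2.

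CXCR5, the receptor used for sorting, stood at 9.92 ± 0.41 log2 units (SD, n = 2) in CXCR5+ cells, 6.09 ± 0.38 in CXCR5− cells and 6.74 ± 0.23 in CD45RA+ cells, or 103, 5.91 and 10.7 RPM. It was higher in CXCR5+ than in CXCR5− cells by 3.82 (SE 0.30, limma adjusted p = 0.0142) and higher than in CD45RA+ cells by 3.18 (SE 0.30, limma adjusted p = 0.00241). CXCR5− and CD45RA+ cells differed by -0.64 without passing (adjusted p = 0.333). CD8A, a chain of the CD8 co-receptor, was higher in CXCR5+ than in CD45RA+ cells by 1.25 (SE 0.23, adjusted p = 0.0223). In CXCR5− cells it stood 0.95 above CD45RA+ cells, with an adjusted p of 0.083, or 0.0458 with the donor as a block. CD8B and PTPRC, the gene of CD45, passed in none of the 3 comparisons, and PTPRC at the level of the gene does not resolve CD45RA. The CXCR5 difference between CXCR5+ and CXCR5− cells was 3.53 without CXCR5+ replicate 1, 4.11 without CXCR5+ replicate 2, 3.55 without CXCR5− replicate 1 and 4.09 without CXCR5− replicate 2, and none of these passed (adjusted p = 0.0583, 0.0767, 0.162 and 0.129).

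The first comparison asked how CXCR5+ cells differ from CXCR5− cells of the same CD45RA− compartment. Besides CXCR5 itself, the genes that passed were lower in CXCR5+ cells, and some of them mark innate-like T cells. ZBTB16, which encodes the innate-like T cell regulator PLZF, stood at 3.89 ± 0.05 log2 units in CXCR5+ and 7.20 ± 0.24 in CXCR5− cells (SD, n = 2; difference -3.31). IL18RAP, a chain of the IL-18 receptor, differed by -2.90 and DPP4, which encodes CD26, by -3.25. IL2RA, the alpha chain of the IL-2 receptor, differed by -3.44 (7.23 against 96.2 RPM), SPRY1, a feedback inhibitor of receptor kinase signalling, by -3.52, LRRN3, a transcript of naive T cells, by -2.85 and PKIA, an inhibitor of protein kinase A, by -2.50. These 7 genes had a limma adjusted p between 0.0142 and 0.0287 and standard errors between 0.23 and 0.33.

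In all, 9 of 16266 genes passed, 1 higher and 8 lower in CXCR5+ cells, and 37 passed with the donor as a block (3 higher and 34 lower), among them the 9. Genes that passed with the block alone included GNLY, the cytolytic protein granulysin (7.94 ± 0.96 against 11.81 ± 0.49, difference -3.88, adjusted p = 0.0876 and 0.0081 with the block). SLAMF1 (-2.27, 0.053 and 0.0252), IL23R, a receptor chain for IL-23 (-2.16, 0.0603 and 0.0358), CASS4 (-2.38, 0.0586 and 0.0252) and HDGFRP3 (-2.08, 0.0529 and 0.0252) did so too. On the other side, the adhesion molecule gene CADM1 stood 2.61 higher in CXCR5+ cells (0.0919 and 0.0252 with the block) and AGAP1 2.06 higher (0.0919 and 0.0287). DKK3, of the Dickkopf family of secreted proteins, stood 2.48 higher. It passed in neither of these fits but did with voom (adjusted p = 0.00738). The count of genes was 2 without CXCR5+ replicate 1, 0 without CXCR5+ replicate 2, 0 without CXCR5− replicate 1 and 1 without CXCR5− replicate 2. The gene called without CXCR5− replicate 2 was not among the 9. None of the 8 genes named above that passed changed sign in these limma fits. With all libraries 873 of 16266 genes had an unadjusted limma p under 0.05, near the share of 0.05 expected without any difference. On all 6 libraries, limma-voom called 65 genes from the recovered reads.

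**Figure D1:**
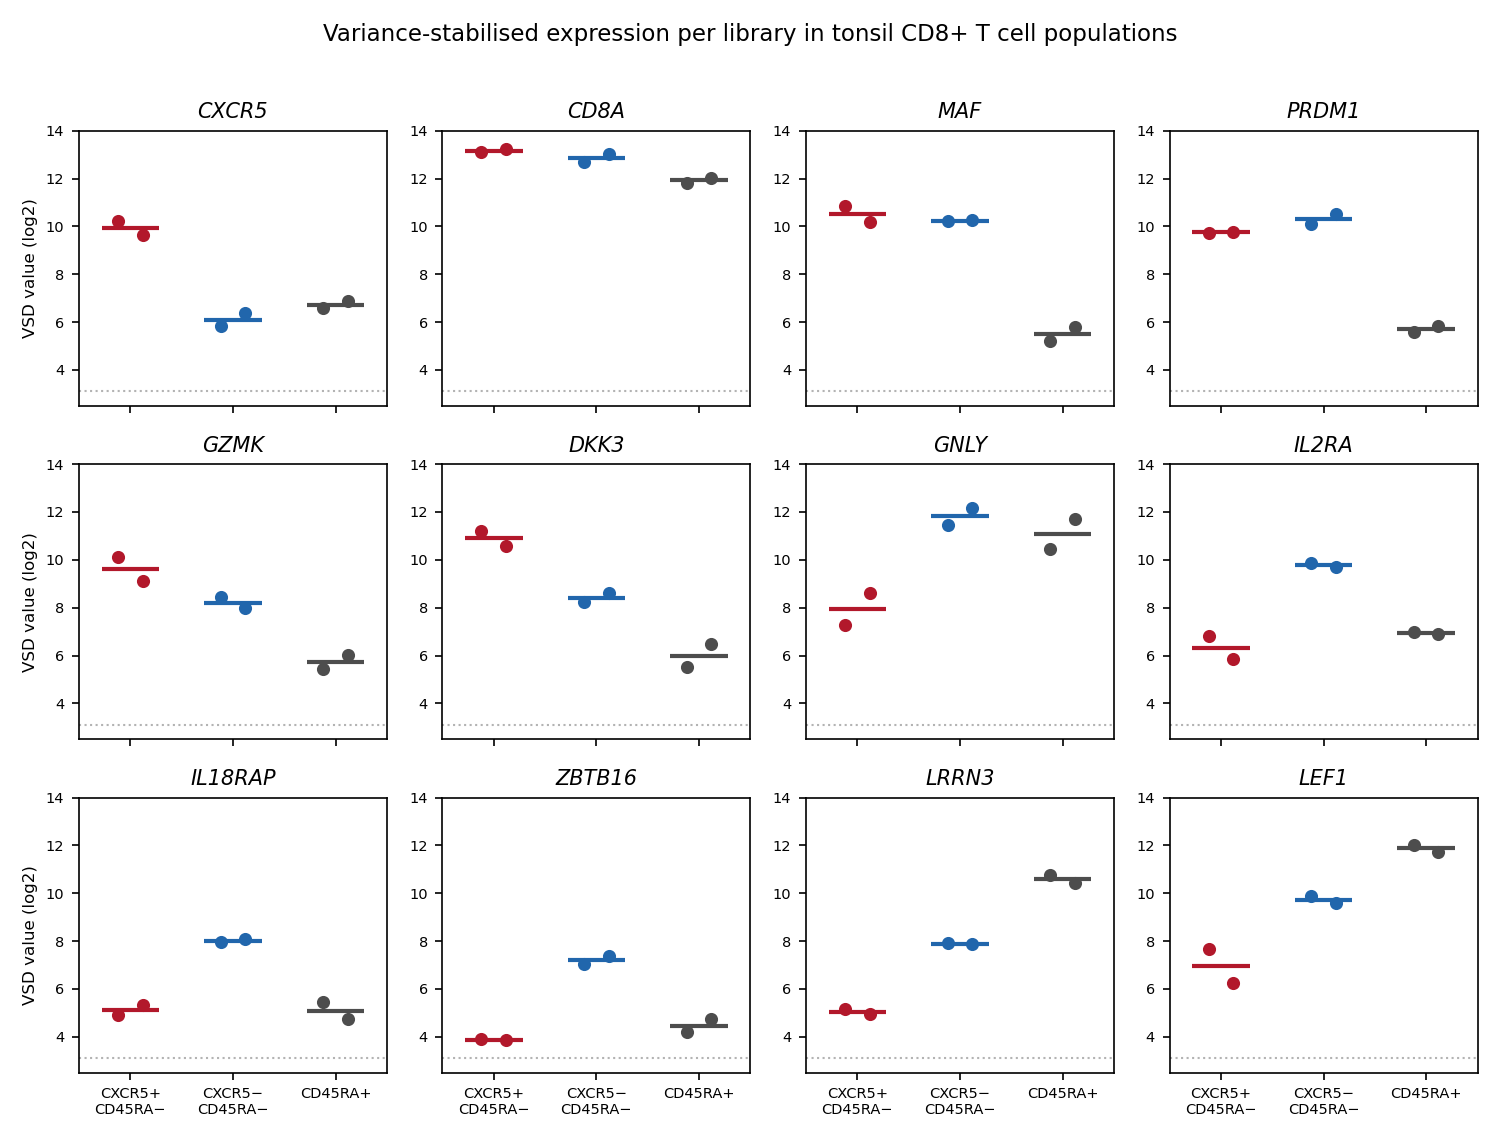
Variance-stabilised values (log2, vertical axis) of 12 genes in the 3 sorted populations (horizontal axis), where each point is 1 library, each bar the mean of the 2 libraries and the dotted line the value of a gene without reads. IL18RAP, ZBTB16 and IL2RA were higher in CXCR5− cells than in both other populations, and LRRN3 was lower in CXCR5+ cells than in both others. The values of GNLY also lay lower in CXCR5+ cells than in both others.

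Innate-like T cell markers lay lower in CXCR5+ than in CXCR5− cells for all 11 tested members, with a median of -1.65. Over all genes 3 passed, ZBTB16 and IL18RAP among them, and 9 members passed when adjusted over the list alone (camera adjusted p = 9.92e-25, and adjusted p = 0.0793 with an estimated correlation). SLC4A10, a marker of mucosal-associated invariant T cells, had 12 against 417 reads (-2.88). It passed with voom (adjusted p = 0.036) but not in the main fit. Of the CD4 and regulatory T cell markers 8 of 10 lay lower, IL2RA passed and 3 passed adjusted over the list alone (camera adjusted p = 2.8e-06, and adjusted p = 0.132 with an estimated correlation). CD4 itself stood at 5.92 RPM in CXCR5+ and 12.1 in CXCR5− cells (-0.78, not passing), against 990 and 838 RPM of CD8A. FOXP3, the regulatory T cell factor, differed by -0.69 and TNFRSF4 by -1.47, neither past the threshold.

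Of the naive and stem-like genes 15 of 23 lay lower in CXCR5+ than in CXCR5− cells, LRRN3 passed and 8 passed adjusted over the list alone (camera adjusted p = 1.31e-07, and adjusted p = 0.132 with an estimated correlation). With the block, 4 passed: LRRN3, LEF1, TXK and MAL. LEF1, a transcription factor of the Wnt pathway, differed by -2.77 (adjusted p = 0.106 and 0.0287 with the block), the kinase gene TXK by -2.39 (0.0606 and 0.0176) and MAL by -2.17 (0.0603 and 0.0252). BACH2, a repressor of effector genes, differed by -1.27 and passed in neither of these fits, but did with voom (adjusted p = 0.0283). Inhibitory receptor and exhaustion genes lay lower for 19 of 21 members, with KLRC1 at -2.03, LAYN at -1.81 and CTLA4 at -1.04. In limma 0 of them passed over all genes, 7 adjusted over the list alone, 8 at an unadjusted p under 0.05 and 1 with voom (camera adjusted p = 1.29e-08, and adjusted p = 0.301 with an estimated correlation).

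Cytokine and chemokine genes lay lower in CXCR5+ than in CXCR5− cells for 25 of 29 members. In limma 0 passed over all genes, 9 adjusted over the list alone, 11 at an unadjusted p under 0.05 and 1 with voom (camera adjusted p = 1.29e-08, and adjusted p = 0.275 with an estimated correlation). IL17F, a cytokine of type 17 cells, had 0 reads in CXCR5+ and 239 in CXCR5− cells, at least 67.2-fold lower against a floor of 3 reads over the group (limma adjusted p = 0.191). That bound was 20.7 without CXCR5+ replicate 1, 46.5 without CXCR5+ replicate 2, 25 without CXCR5− replicate 1 and 246 without CXCR5− replicate 2. In the last case limma cannot test IL17F, since the replicates left to give a spread all had 0 reads. CSF2, the growth factor GM-CSF, had 5 against 376 reads and did not pass. CCL20, a ligand of CCR6, had 5 against 107 reads (-2.35, adjusted p = 0.197 and 0.0252 with the block). NK cell markers lay lower for 12 of 13 members, with XCL1 at -1.52. In limma 0 passed over all genes, 1 adjusted over the list alone, 2 at an unadjusted p under 0.05 and 1 with voom (camera adjusted p = 4.62e-04, and adjusted p = 0.283 with an estimated correlation). Tissue residency genes lay lower for 12 of 19 members, with AHR at -1.02. In limma 0 passed over all genes or adjusted over the list alone, 4 at an unadjusted p under 0.05 and 0 with voom (camera adjusted p = 0.0146, and adjusted p = 0.438 with an estimated correlation). The residency call was lost without CXCR5+ replicate 2 (adjusted p = 0.22) and without CXCR5− replicate 2 (0.258).

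Oxidative phosphorylation genes lay higher in CXCR5+ than in CXCR5− cells for 25 of 30 members, with a median of 0.19 and with NDUFA1 at 0.78 and UQCRB at 0.65. In limma 0 passed over all genes or adjusted over the list alone, 4 at an unadjusted p under 0.05 and 0 with voom (camera adjusted p = 4.24e-04, and adjusted p = 0.283 with an estimated correlation). Replication-dependent histone genes lay higher for 14 of 18 members, with a median of 0.35 and with HIST2H2AC at 0.77 and HIST1H3D at 0.75. In limma 0 passed over all genes or adjusted over the list alone, 5 at an unadjusted p under 0.05 and 0 with voom (camera adjusted p = 1.15e-04, and adjusted p = 0.438 with an estimated correlation). The histone call was lost without CXCR5+ replicate 1 (adjusted p = 0.0577) and without CXCR5− replicate 2 (0.075).

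T follicular helper genes made no call between CXCR5+ and CXCR5− cells (camera adjusted p = 0.923). Their 1 member past the threshold was CXCR5, while 2 were higher and 3 lower adjusted over the list alone. Cytotoxic genes made none either (0.509), with 1 higher and 6 lower adjusted over the list alone and 3 lower with voom. GZMB, granzyme B, stood at -2.08 and passed with voom (adjusted p = 0.0329) but not in the main fit. For the other lists the camera adjusted p was 0.903 for T cell identity, 0.523 for activation and immediate early genes, 0.248 for cell cycle, 0.839 for chemokine receptors and homing, 0.21 for glycolysis, 0.428 for B cell, 0.956 for plasma cell, 0.69 for myeloid and 0.903 for epithelial and stromal markers. MS4A1, which encodes the B cell antigen CD20, had 89 reads in CXCR5+ and 22 in CXCR5− cells (1.13, adjusted p = 0.325). The mean and the test differed in sign for T follicular helper genes (mean 0.03, tested downward), chemokine receptors (0.03, downward) and epithelial and stromal markers (0.06, downward). Leaving out 1 library moved several of these lists. Such fits leave the donors uneven, so they cannot tell an odd library from a difference between donors. Without CXCR5+ replicate 1, activation (0.0271) and chemokine receptor genes (0.0216) passed downward, without CXCR5− replicate 1 glycolysis did (0.013), and without CXCR5− replicate 2 cell cycle genes did (0.00647). Interferon response genes (0.62) lay downward without CXCR5+ replicate 1 or CXCR5− replicate 2. They lay upward without CXCR5+ replicate 2 or CXCR5− replicate 1. Higher values in the donor of the replicates 1, in both populations, would give these turns. The estimated correlation of this list was 0.942, far above the preset of 0.01.

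The second comparison set CXCR5+ cells against CD45RA+ cells. The transcription factor gene MAF stood at 10.51 ± 0.47 log2 units in CXCR5+ and 5.50 ± 0.41 in CD45RA+ cells (SD, n = 2; difference 5.01, 157 against 3.58 RPM). DKK3 was higher by 4.89, the chemokine receptor gene CCR4 by 4.77, CADM1 by 4.43, the phosphatase gene DUSP4 by 4.05 and PRDM1, which encodes the effector regulator Blimp-1, by 4.04. LRRN3 stood at 5.05 ± 0.13 and 10.59 ± 0.26 (-5.55), and the other large differences downward were ACTN1 (-5.21), LEF1 (-4.94), CA6 (-4.75), IGF1R (-4.66), TXK (-4.38) and NOG (-4.14). The interferon-inducible genes GBP5 (-4.01) and GBP1 (-3.83) were lower too, GBP5 with 121 RPM in CXCR5+ and 2136 in CD45RA+ cells. These genes had a limma adjusted p between 3.65e-04 and 0.00441 and standard errors between 0.23 and 0.47.

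Of 16266 genes 1142 passed, 553 higher and 589 lower in CXCR5+ than in CD45RA+ cells, and 1861 passed with the donor as a block (969 higher and 892 lower), among them the 1142. The count was 423 without CXCR5+ replicate 1, 420 without CXCR5+ replicate 2, 444 without CD45RA+ replicate 1 and 721 without CD45RA+ replicate 2, the shallowest library. Of 49 genes of this comparison that passed and were followed through the fits with 1 library left out, some lost their call and none changed sign. With voom and reads scaled by their totals, 37.6% of 1791 calls were higher, against 48.4% in the limma fit, and the median difference of all genes was -0.186, against 0.019.

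Cytotoxic genes were higher in CXCR5+ than in CD45RA+ cells for 14 of 28 members and lower for 1 (19 and 1 adjusted over the list alone). Of the 3 members with a lower mean, GNLY was the 1 called lower, at 7.94 log2 units in CXCR5+ and 11.08 in CD45RA+ cells. The granzyme genes GZMK, GZMA and GZMH were higher by 3.87, 3.41 and 3.27 and PRF1, the pore-forming protein perforin, by 1.61 (camera adjusted p = 1.02e-10, and adjusted p = 0.259 with an estimated correlation). T follicular helper genes were higher for 10 of 28 members and lower for 2 (14 and 5 adjusted over the list alone). The 10 include CXCR5, whose rise the sort itself set. Of the T follicular helper genes, PDCD1, which encodes PD-1, had 63.7 against 8.05 RPM, TOX was higher by 3.01 and CXCL13, the gene of the CXCR5 ligand, by 2.09 (camera adjusted p = 3.28e-04, and adjusted p = 0.346 with an estimated correlation). Inhibitory receptor genes were higher for 6 of 21 members and lower for 1 (9 and 4 adjusted over the list alone), with LAG3 higher by 3.32, CTLA4 by 1.58 and LAYN at -2.96 (camera adjusted p = 0.0113, and adjusted p = 0.534 with an estimated correlation). That list call was lost without CD45RA+ replicate 1 (adjusted p = 0.0977). Tissue residency genes were higher for 6 of 19 members (7 adjusted over the list alone), with ITGAE, which encodes CD103, higher by 3.60 and CXCR6 by 2.63 (camera adjusted p = 5.13e-04, and adjusted p = 0.346 with an estimated correlation). Chemokine receptor and homing genes were higher for 9 members, CXCR5 again among them, and lower for 3 of 26 (12 and 3 adjusted over the list alone). Their camera adjusted p was 0.00124, and 0.487 with an estimated correlation.

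Activation and immediate early genes were higher in CXCR5+ than in CD45RA+ cells for 12 of 26 members and lower for 2 (13 and 2 adjusted over the list alone). FOS, JUN and FOSB, of the AP-1 family, were higher by 3.34, 3.27 and 3.04 (camera adjusted p = 9.17e-07, and adjusted p = 0.348 with an estimated correlation). Cell cycle genes were higher for 5 of 31 members (8 adjusted over the list alone), with the spindle protein genes NUSAP1 and TPX2 both higher by 1.86 (camera adjusted p = 4.24e-05, and adjusted p = 0.346 with an estimated correlation). Histone genes were higher for 8 of 18 members (13 adjusted over the list alone), with HIST2H3D higher by 2.31 and HIST1H3H by 1.60 (camera adjusted p = 3.61e-08, and adjusted p = 0.346 with an estimated correlation). Cytokine and chemokine genes were higher for 6 of 29 members and lower for 2 (13 and 6 adjusted over the list alone), with TNFSF9, the ligand of 4-1BB, higher by 3.54, CCL4 by 2.22 and CSF2 at -2.96, a call lost with voom (0.0902) (camera adjusted p = 0.0198, and adjusted p = 0.487 with an estimated correlation). The cytokine call was lost with the stricter filter (adjusted p = 0.108). CD4 and regulatory T cell markers were higher for 4 of 10 members (5 adjusted over the list alone), with CD4 at 5.92 against 0.386 RPM (camera adjusted p = 0.00135, and adjusted p = 0.259 with an estimated correlation). Naive and stem-like genes were lower for 13 of 23 members (17 lower and 3 higher adjusted over the list alone), among them MYB at -3.24 (camera adjusted p = 6.24e-11, and adjusted p = 0.213 with an estimated correlation).

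The remaining lists made no call between CXCR5+ and CD45RA+ cells, with a camera adjusted p of 0.639 for T cell identity, 0.325 for interferon response, 0.0594 for oxidative phosphorylation, 0.187 for glycolysis, 0.085 for B cell, 0.183 for plasma cell, 0.577 for NK cell, 0.711 for innate-like T cell, 0.577 for myeloid and 0.258 for epithelial and stromal markers. Single members passed. PDK1, a kinase that restrains pyruvate oxidation, differed by -1.95 and the glucose transporter gene SLC2A1 was higher by 1.29. CR2 (-2.51) and RALGPS2 (-2.21) of the B cell list, FCER1G (-2.08) of the NK cell list and NCR3 (-1.24) of the innate-like list were lower in CXCR5+ cells, NCR3 not with voom (0.0575). CDH1 of the epithelial list was higher by 2.87, and OASL of the interferon list by 1.97. Of the 27 interferon members 1 other passed, and it was lower. The median and the test differed in sign for T cell identity (median -0.02, tested upward) and innate-like T cell markers (0.03, downward). Interferon response genes passed downward without CXCR5+ replicate 1 (4.53e-05) and without CD45RA+ replicate 2 (0.00969). Without CXCR5+ replicate 2, oxidative phosphorylation (0.0288) and plasma cell genes (0.0379) passed upward and B cell markers downward (0.0335).

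The third comparison set CXCR5− cells against CD45RA+ cells. MAF stood at 10.24 ± 0.03 log2 units in CXCR5− and 5.50 ± 0.41 in CD45RA+ cells (SD, n = 2; difference 4.75), and PRDM1 was higher by 4.59, CCR4 by 4.36, the metalloprotease gene ADAM19 by 3.91 and LAG3 by 3.83. The type 17 cytokine gene IL17F was higher as well, with 239 reads in CXCR5− and 0 in CD45RA+ cells, at least 30.2-fold higher against a floor of 3 reads over the group. That bound was 11.3 without CXCR5− replicate 1, 111 without CXCR5− replicate 2, 9.57 without CD45RA+ replicate 1 and 20.7 without CD45RA+ replicate 2. IL17F varied widely between the CXCR5− libraries (6.75 ± 1.87, limma adjusted p = 0.0451). Its call was lost with voom (0.138) and without any 1 library other than CXCR5− replicate 2. Without CXCR5− replicate 2 the replicates left to give a spread all had 0 reads, so that fit cannot test IL17F. CD4 was higher by 3.21, at 12.1 against 0.386 RPM. Lower in CXCR5− cells were ACTN1 (-4.20), the adhesion molecule gene NRCAM (-3.74), NOG (-3.67), CA6 (-3.13), GBP1 (-3.08), IGF1R (-3.01), GBP5 (-2.91) and LRRN3 (-2.70). These genes had a limma adjusted p between 0.00194 and 0.0451 and standard errors between 0.23 and 0.71.

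In total 444 of 16266 genes passed, 254 higher and 190 lower in CXCR5− than in CD45RA+ cells, and 942 passed with the donor as a block (554 higher and 388 lower), among them the 444. The count was 4 without CXCR5− replicate 1, 2 without CXCR5− replicate 2 and 81 without CD45RA+ replicate 1. Of 43 genes of this comparison that passed and were followed through the fits with 1 library left out, most lost their call without a CXCR5− library. None of the 43 changed sign. The count without CXCR5− replicate 2 includes IL17F, which that fit cannot test. With voom and reads scaled by their totals, 42.9% of 1018 calls were higher, against 57.2% in the limma fit, and the median difference of all genes was -0.124, against 0.023.

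Innate-like T cell markers were higher in CXCR5− than in CD45RA+ cells for 6 of 11 members (10 adjusted over the list alone). SLC4A10 was higher by 3.17, IL18RAP by 2.93 and ZBTB16 by 2.72 (camera adjusted p = 7.36e-12, and adjusted p = 0.0813 with an estimated correlation). CD4 and regulatory T cell markers were higher for 7 of 10 members (8 adjusted over the list alone), including IL2RA by 2.83, CTLA4 by 2.62, TNFRSF4 by 2.21 and FOXP3 by 1.63 (camera adjusted p = 3.32e-10, and adjusted p = 0.0813 with an estimated correlation). Cytokine and chemokine genes were higher for 12 of 29 members (18 higher and 2 lower adjusted over the list alone), with CCL3 higher by 2.27 (camera adjusted p = 6.19e-11, and adjusted p = 0.138 with an estimated correlation). Cytotoxic genes were higher for 11 of 28 members (20 adjusted over the list alone), with GZMH at 14.5 against 0.600 RPM, GZMA higher by 2.79 and PRF1 by 2.33 (camera adjusted p = 6.21e-18, and adjusted p = 0.0846 with an estimated correlation). Inhibitory receptor genes were higher for 6 of 21 members (15 higher and 1 lower adjusted over the list alone), with PDCD1 higher by 3.18 and HAVCR2, which encodes TIM-3, by 2.25 (camera adjusted p = 5.01e-10, and adjusted p = 0.198 with an estimated correlation).

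T follicular helper genes were higher in CXCR5− than in CD45RA+ cells for 8 of 28 members and lower for 1 (13 and 3 adjusted over the list alone), with CXCL13 higher by 1.96, a call lost with voom (0.0672), and the cytokine receptor gene IL6ST at -1.28 (camera adjusted p = 9.08e-06, and adjusted p = 0.198 with an estimated correlation). Tissue residency genes were higher for 4 of 19 members (10 adjusted over the list alone), with CXCR6 higher by 2.51 (camera adjusted p = 5.85e-10, and adjusted p = 0.122 with an estimated correlation). ITGAE stood 2.78 higher, with an adjusted p of 0.0524, or 0.0229 with the block. Activation and immediate early genes were higher for 10 of 26 members (16 adjusted over the list alone), with DUSP4 higher by 3.68, FOS by 2.64 and ATF3 by 2.15 (camera adjusted p = 1.54e-12, and adjusted p = 0.188 with an estimated correlation). Cell cycle genes were higher for 5 of 31 members (11 adjusted over the list alone), with TPX2 higher by 2.21 and CENPF by 1.98 (camera adjusted p = 6.76e-08, and adjusted p = 0.138 with an estimated correlation). Chemokine receptor genes were higher for 4 of 26 members (15 higher and 3 lower adjusted over the list alone), with CCR2 higher by 2.56 (camera adjusted p = 8.7e-05, and adjusted p = 0.315 with an estimated correlation). Of 18 histone genes HIST1H3H was higher, by 1.72, and 8 passed adjusted over the list alone (camera adjusted p = 1.24e-05, and adjusted p = 0.283 with an estimated correlation).

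The glycolysis list passed upward in CXCR5− against CD45RA+ cells (camera adjusted p = 0.0104, and adjusted p = 0.315 with an estimated correlation), but not without CXCR5− replicate 2 (0.104). Its 1 member past the threshold went the other way: PDK1 differed by -1.84, and adjusted over the list alone 5 were higher and 1 lower. PGAM1, a glycolytic enzyme gene, stood 1.64 higher (adjusted p = 0.0591 and 0.0137 with the block). Naive and stem-like genes were lower for 8 of 23 members (12 adjusted over the list alone), among them MYB at -2.38 (camera adjusted p = 6.19e-11, and adjusted p = 0.0813 with an estimated correlation). CR2 (-2.52) and RALGPS2 (-1.89) of the B cell list and FCER1G (-1.51) of the NK cell list were lower in CXCR5− cells.

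The other lists made no call between CXCR5− and CD45RA+ cells, with a camera adjusted p of 0.799 for T cell identity, 0.849 for oxidative phosphorylation, 0.124 for B cell, 0.124 for plasma cell, 0.157 for NK cell, 0.849 for myeloid and 0.068 for epithelial and stromal markers. The interferon response list had an adjusted p of 0.0861, and of 5.03e-04, downward, with the block. It also passed downward with the compared libraries alone (0.0407), which is the same fit as leaving out either CXCR5+ library. Epithelial and stromal markers passed upward in that fit (0.0452). Leaving out 1 of the compared libraries also moved the calls of the interferon response, epithelial and stromal, and NK cell lists. The median and the test differed in sign for oxidative phosphorylation (0.09, tested downward) and myeloid markers (0.03, downward).

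**Figure D2:**
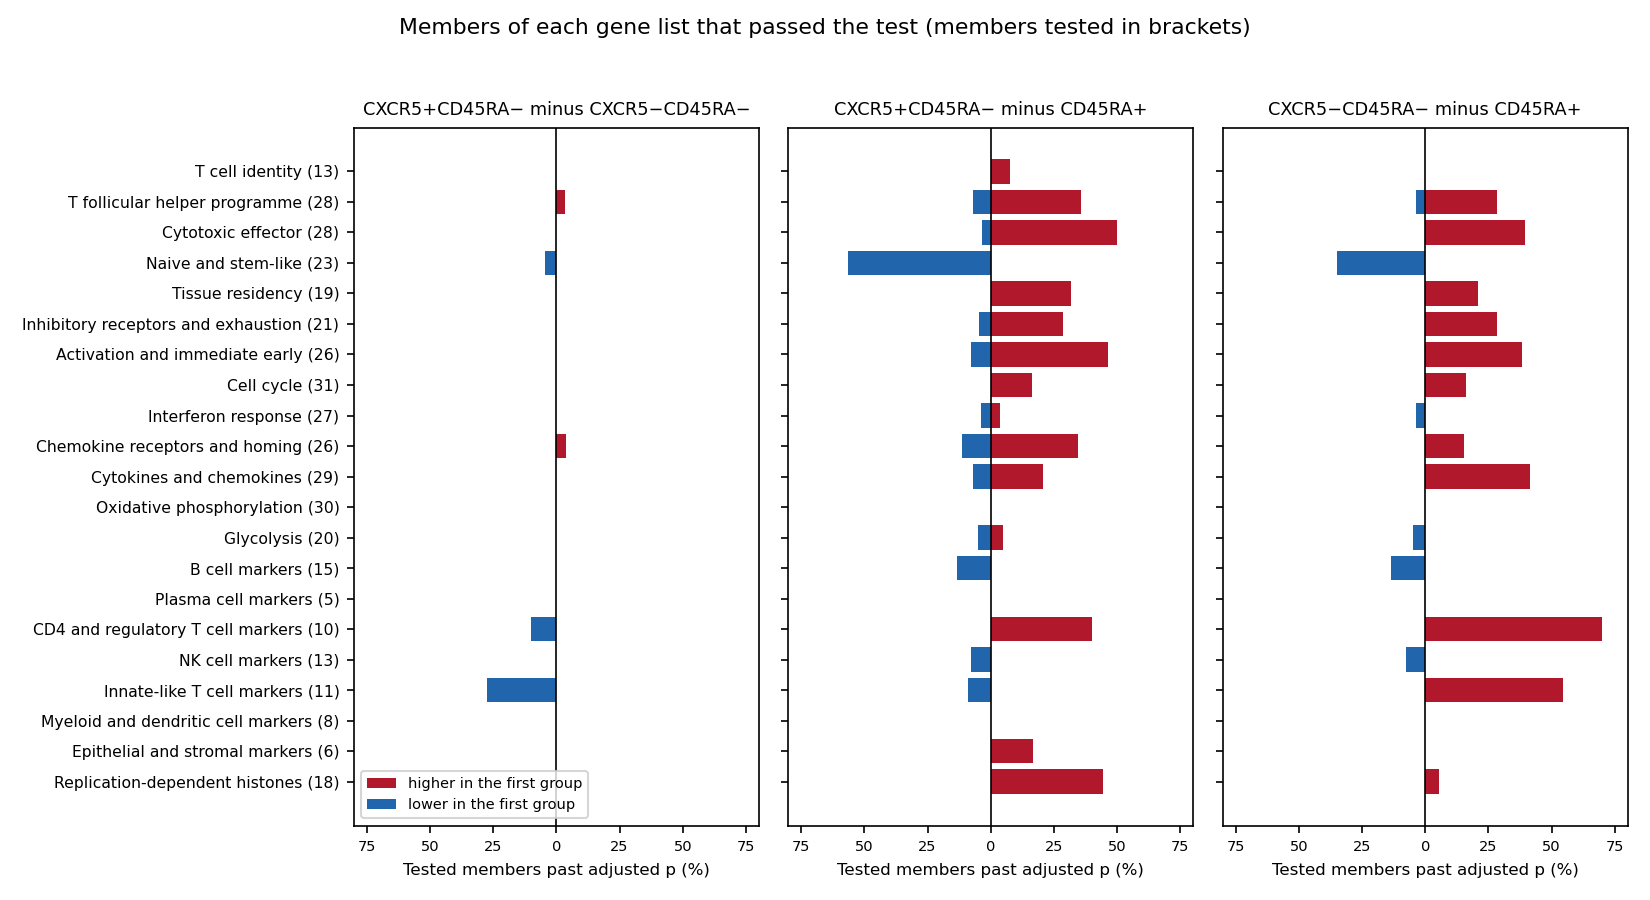
Share of the tested members of each gene list that passed limma's threshold (horizontal axis, percent), drawn to the right where higher and to the left where lower in the first population of the pair, with the members tested in brackets. Between CXCR5+ and CXCR5− cells 3 of 11 innate-like T cell markers were lower, and naive and stem-like genes were lower than in CD45RA+ cells for 13 of 23 members in CXCR5+ and 8 of 23 in CXCR5− cells.

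The comparisons with CD45RA+ cells used the same CD45RA+ libraries. Of the 553 and 254 genes higher than in CD45RA+ cells in CXCR5+ and CXCR5− cells, 194 were shared, and of the 589 and 190 lower genes 181 were shared. In limma 0 genes passed in opposite directions. Independent lists of these sizes would share 8.64 and 6.88 genes. The controls were then split, with a different CD45RA+ library in each comparison. With replicate 1 for CXCR5+ and replicate 2 for CXCR5− cells, 26 of 427 and 47 higher genes and 31 of 294 and 34 lower genes were shared, against 1.23 and 0.615 for independent lists. With the libraries exchanged, 113 of 196 and 247 higher and 73 of 248 and 96 lower genes were shared, against 2.98 and 1.46. This split was made after the overlap was seen, and the CXCR5+ and CXCR5− libraries still came from the same 2 donors. The fits compared also shared their estimate of the spread of each gene, after the split from the same CD45RA− libraries. Genes of small spread can thus pass in both, so independent lists are no fair baseline before or after the split.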

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

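The tests in this part were planned, and the genes were picked afterwards by the sign of their difference from CD45RA+ cells. Of the genes named that passed between CXCR5+ and CXCR5− cells, 5 had differences from CD45RA+ cells of opposite sign in those populations. The direct comparison tests CXCR5+ against CXCR5− cells and not the place of CD45RA+ cells between them. For none of these 5 genes did both differences from CD45RA+ cells pass. CXCR5 differed by 3.82 log2 units (limma adjusted p = 0.0142), at 3.18 against CD45RA+ cells in CXCR5+ cells and -0.64 in CXCR5− cells. ZBTB16 differed by -3.31 (0.0142) and IL2RA by -3.44 (0.0203). These genes were higher than in CD45RA+ cells in CXCR5− cells, by 2.72 and 2.83, and stood at -0.58 and -0.61 in CXCR5+ cells without passing. SPRY1 differed by -3.52 (0.0166) and DPP4 by -3.25 (0.0203). Both were lower than in CD45RA+ cells in CXCR5+ cells (-2.36 and -1.96), while their values of 1.16 and 1.29 in CXCR5− cells did not pass. Each of these 5 calls was lost without CXCR5+ replicate 2, CXCR5− replicate 1 or CXCR5− replicate 2, and without CXCR5+ replicate 1 those of SPRY1 and IL2RA alone were kept.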

How the results depend on the processing

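The voom tests on recovered reads were chosen after seeing the data, and the other alternatives were planned. Between CXCR5+ and CXCR5− cells, the count of 9 genes became 37 with the replicate block, 32 with the stricter filter, 54 with an intensity trend, 65 with voom, 88 with voom scaled by total reads and 306 with voom and the replicate block, and lay between 0 and 13 when 1 library was left out. Against CD45RA+ cells, the count of 1142 for CXCR5+ cells became 1861 with the replicate block, 1791 with voom scaled by total reads and 3582 with voom and the block, and lay between 420 and 828 with 1 library left out. For CXCR5− cells, 444 became 942 with the replicate block, 795 with a trend, 824 with voom, 1018 with voom scaled by total reads and 2022 with voom and the block, and lay between 2 and 373. The sort marker CXCR5 kept its sign throughout, and its difference between CXCR5+ and CXCR5− cells lay between 3.53 and 4.11 with 1 library left out, where fits without a CXCR5+ or CXCR5− library no longer passed. With an estimated correlation 0 lists passed in each comparison, against 9, 11 and 13 at the preset correlation. Fry called 3, 9 and 11 lists. Between CXCR5+ and CXCR5− cells fry lost the residency (adjusted p = 0.405), inhibitory receptor (0.322) and cytokine (0.285) calls. It lost those of oxidative phosphorylation (0.285), NK cell markers (0.322) and histones (0.405) too. For CXCR5+ against CD45RA+ cells it lost inhibitory receptors (0.177), chemokine receptors (0.072) and cytokines (0.177). For CXCR5− against CD45RA+ cells it lost chemokine receptors (0.056), glycolysis (0.118) and histones (0.056). Leaving out a library leaves fewer samples and can leave the donors uneven, and the cause of the other moves was not tested. The genes followed through the alternatives were those that the Results give in a comparison, apart from GNLY against CD45RA+ cells. Genes given against CD45RA+ cells only in the flagged and closing parts were not followed. Beyond the calls given with it in the report, the replicate block on the deposited values changed no list call. It also changed no further call of a gene followed. With voom and the block, the cytokine call of CXCR5+ against CD45RA+ cells was lost (adjusted p = 0.0714). Lists without a call passed in other tests as well. Between CXCR5+ and CXCR5− cells these were interferon response upward with voom (0.0498) and scaling by totals (0.00494), glycolysis downward with quantile normalisation (0.0468) and scaling by totals (0.0362), and B cell markers downward with the stricter filter (0.0193). For CXCR5+ against CD45RA+ cells they were B cell markers downward with the stricter filter (0.0117) and fry (0.04) and epithelial and stromal markers upward with no filter (0.0297). For CXCR5− against CD45RA+ cells interferon response passed downward with no filter (0.0442), the compared libraries alone (0.0407), voom (0.00446), scaling by totals (0.00931) and voom with the block (4.00e-04). There, B cell markers passed downward with fry (0.0361), NK cell markers passed upward with the stricter filter (0.00632), scaling by totals (0.0311) and voom with the block (0.0432), and epithelial and stromal markers upward with the stricter filter (0.0303) and the compared libraries alone (0.0452).

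PTPRC, which passed in no comparison, changed sign against CD45RA+ cells for CXCR5+ cells with quantile normalisation (-0.086) and with voom scaled by total reads (-0.068), with a range of -0.042 to 0.217 without 1 library, and for CXCR5− cells within -0.194 to 0.063. No other gene followed through the alternatives changed sign. Calls that genes gained in the alternatives are not listed in full here. For the genes followed, calls were lost as follows, apart from those with 1 library left out. Between CXCR5+ and CXCR5− cells this was IL18RAP with median centring (adjusted p = 0.0628). For CXCR5+ against CD45RA+ cells these were CSF2 with voom (0.0902) and scaling by totals (0.0962), NCR3 with voom (0.0575), TPX2 (0.0508) and CD4 (0.0529) with scaling by totals, SLC2A1 with no filter (0.0518) and the compared libraries alone (0.0538), and OASL with the compared libraries alone (0.0626). For CXCR5− against CD45RA+ cells these were IL17F with quantile normalisation (0.0659), median centring (0.0632), the compared libraries alone (0.0583), voom (0.138) and scaling by totals (0.165), CXCL13 with voom (0.0672) and scaling by totals (0.0751), IL6ST with the compared libraries alone (0.0553), and FCER1G with no filter (0.0591) and a trend (0.0505). Lists without a call turned direction as follows, given as adjusted p. Between CXCR5+ and CXCR5− cells these were T cell identity with quantile normalisation (0.774) and scaling by totals (0.864), T follicular helper with scaling by totals (0.864), voom with the block (0.83) and fry (0.942), chemokine receptors with the stricter filter (0.993), scaling by totals (0.954) and fry (0.942), plasma cell with the stricter filter (0.586) and quantile normalisation (0.936), and epithelial and stromal with no filter (0.0881), quantile normalisation (0.936), voom (0.617), scaling by totals (0.53) and voom with the block (0.616). Against CD45RA+ cells they were, for CXCR5+ cells, T cell identity (0.845) and innate-like (0.937) with quantile normalisation, NK cell with the stricter filter (0.703) and myeloid with no filter (0.976), and for CXCR5− cells T cell identity with quantile normalisation (0.87), oxidative phosphorylation with voom (0.939), voom with the block (0.948) and fry (0.983), and myeloid with no filter (0.498), the stricter filter (0.885), quantile normalisation (0.87) and scaling by totals (0.989).

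Leaving out 1 library also turned lists. Between CXCR5+ and CXCR5− cells the adjusted p ranged from 0.54 to 0.941 for T cell identity, 0.653 to 0.968 for T follicular helper, 0.0271 to 0.976 for activation, 0.00647 to 0.929 for cell cycle, 4.1e-08 to 0.604 for interferon response, 0.0216 to 0.931 for chemokine receptors, 0.236 to 0.968 for plasma cell, 0.351 to 0.957 for myeloid and 0.118 to 0.991 for epithelial and stromal markers. Against CD45RA+ cells it ranged for CXCR5+ cells from 4.53e-05 to 0.52 for interferon response, 0.121 to 0.936 for NK cell and 0.41 to 0.89 for innate-like markers, and for CXCR5− cells from 0.536 to 0.954 for T cell identity, 8.22e-05 to 0.855 for interferon response and 0.6 to 0.968 for oxidative phosphorylation. Symbols with 0 reads numbered 5669 in the shallowest library and between 2614 and 3229 in the other 5.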

Other observations

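The tests of library depth, CD4 T cells, B cells and the shallow library were chosen after the results they bear on were seen, and the test of the interferon-gamma list was set before its result was seen. GBP1 and GBP5, which interferon-gamma induces, were lower in both CD45RA− populations than in CD45RA+ cells. On a list of 34 interferon-gamma type response genes without GBP1, GBP4 and GBP5, 24 of 31 tested members lay lower in CXCR5+ than in CD45RA+ cells and 25 of 31 in CXCR5− cells, with medians of -0.41 and -0.42. Over all genes, 5 were lower and 2 higher in CXCR5+ cells, and 4 lower and 2 higher in CXCR5− cells. In CXCR5+ and CXCR5− cells GBP2 differed by -1.77 and -1.40 (limma adjusted p = 0.00647 and 0.0252), APOL6 by -1.61 and -1.40 (0.0133 and 0.0374) and UBE2L6 by -1.31 and -1.48 (0.0285 and 0.0323). Against that direction, CIITA, the regulator of MHC class II genes, was higher by 2.06 and 2.08 (0.0066 and 0.0139) and SOCS3 by 1.61 and 1.29 (0.0123 and 0.0441). These members were picked after their values were seen.

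A candidate explanation for GBP1 and GBP5 is a stronger interferon-gamma type response in the sorted CD45RA+ cells. The list passed downward in both CD45RA− populations with a camera adjusted p of 9.54e-05, but not with an estimated correlation (adjusted p = 0.179). The shallow CD45RA+ replicate 2 alone is argued against, since without it the median of the 2 genes was -3.88 in CXCR5+ and -2.95 in CXCR5− cells, against -3.92 and -2.99 with all libraries. Whether this belongs to naive cells or to these tonsils was not tested.

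Innate-like T cell markers lower in CXCR5+ than in CXCR5− cells may reflect fewer mucosal-associated invariant or type 17 cells in the CXCR5+ gate, or lower transcript levels within the same cells, which pooled libraries did not test. Library depth is argued against, because after thinning each library to 3596048 reads the median over the 11 members was -1.835 in the donor with the deeper CXCR5+ library and -1.934 in the donor with the deeper CXCR5− library. CD4 T cells left in the CXCR5− sort stay open: CD4 differed by -0.78 without passing, at 5.92 against 12.1 RPM, and the gate on CD8 would remove such cells.

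MS4A1 had a higher share of the reads in CXCR5+ than in CXCR5− cells of both donors, by ratios of 2.99 (95% exact binomial counting interval 1.37 to 7.73) and 5.19 (2.63 to 10.6), although limma did not call it. B cells left in the CXCR5+ sort could raise it, and the gate on CD8 would remove them. They stay open: the summed share of CD22, CD79A, CD79B and PAX5 had ratios of 0.702 and 0.779, with upper bounds of 1.05 and 1.12, but the sum rests on CD79A and CD79B. By donor the ratios were 0.722 (0.411 to 1.31) and 0.44 (0.211 to 0.831) for CD79A, 0.545 (0.254 to 1.22) and 0.706 (0.343 to 1.34) for CD79B, 1.14 (0.359 to 4.77) and 3.74 (0.951 to 15.5) for CD22, and 0.653 (0.204 to 2.44) and 2.08 (0.737 to 5.53) for PAX5, the last 2 genes with 4 to 14 reads per library. Expression of MS4A1 by some CXCR5+CD8+ T cells is a hypothesis that was not tested.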
